A study of Mus musculus with 32 samples.

How the data were processed

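Total RNA sequencing libraries were made from the gastrocnemius, quadriceps and tibialis of male mice aged up to 3 months, with 4 mice per state stated in the labels. Each library was placed in a group by its labels for muscle, genotype and phenotype, which gave 9 groups of 3 or 4 libraries and 32 libraries in all. Replicate numbers come from the labels. The labels do not say which libraries of different muscles came from 1 mouse, so p-values measure the spread between these libraries. Replicates of a group differed beyond sampling noise in all 42 pairs (chi-square per gene 13.5 to 221), so each library was counted as 1 sample.

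The deposited table gives, per the file headers, a raw count for each gene and library, the same counts after scaling by the authors, and the authors' own log2 fold changes and p-values for comparisons of groups. The raw values of the 32 libraries are whole numbers. They were checked to equal the scaled values times 1 factor per library, and the factors equal median-of-ratios size factors over all 32 libraries. Per the submitters' processing notes, the tools were cutadapt 1.18 for trimming, TopHat2 2.1.1, HTSeq 0.6.0 and DESeq2 1.22.1, and the genome build was GRCm38. Their settings, the strand option of the counting and the release of the annotation are not given in the sources used here. Reads of a gene and of an overlapping or antisense gene may therefore not be told apart, and counts of near-identical copies such as Vcp-rs and Vcp are uncertain. Of 54838 genes listed, 6252 carried no value in any library. They make up 25 classes, such as transfer RNA, ribosomal RNA and antigen receptor genes, and are not analysed here. The other 48586 had counts, 11359 of them with no read in any library, and 25234 had scaled counts. Gene symbols and GRCm38 coordinates were taken from GENCODE vM21, which holds 54723 of the 54838 identifiers.

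The test written down before the data were examined was a quasi-likelihood test on counts. The table marks missing values in a way that kept the raw columns from being classed as counts here, so that test and a count model as its alternative were not run, and limma-voom was used in their place. Counts were analysed in R 4.3.3 with limma 3.58.1. Within each muscle, a gene was tested if its CPM (counts scaled to a common library total) reached the level of 10 counts in a library of median size in as many libraries as the smallest group holds, and its summed count was at least 15. Totals were scaled by the trimmed mean of M values (TMM, trims of 0.3 and 0.05), and 0.5 was added to each count before the logarithm. Linear models with a mean per group, voom weights and robust moderation of the variances gave log2 fold changes, standard errors and p-values with Benjamini-Hochberg adjustment within each comparison. All adjusted p-values of genes are from limma, and 0.05 was the threshold. The 3 states of a muscle share a model. Sick knock-in was compared with wild type, healthy knock-in with wild type, and sick with healthy knock-in. A model of all 32 libraries tested whether a change differs between muscles, and a model of the 12 wild-type libraries compared the muscles. CPM are given on TMM-scaled totals, as mean ± SD per group. Total counts ran from 7685164 to 42588233 per library, so that 1 count is worth more in some libraries than in others, and genes near 0 in a group are given as summed counts. A fold against a group with no read was computed against 3 counts over the group and is a lower bound that covers counting error only.

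The 39 gene lists were fixed with the design. They cover atrophy, glucocorticoid response, lysosome and autophagy, p53 targets, the growth hormone and insulin-like growth factor axis, integrated stress response, endoplasmic reticulum chaperones, cytosolic heat shock, immediate early, acute phase, interferon, circadian clock and cell cycle genes, the sialic acid pathway, extracellular matrix, ribosomal proteins, nuclear oxidative phosphorylation, the mitochondrial genome, fatty acid oxidation, glycolysis, sterol and fatty acid synthesis, fast and slow fibres, sarcomere, excitation-contraction coupling, embryonic fibres, neuromuscular junction and the dystrophin complex. The other lists are markers of satellite cells, fibro-adipogenic progenitors, tendon, macrophages, neutrophils, lymphocytes, erythrocytes, adipocytes, endothelium, smooth muscle and Schwann cells. For each list the members past 0.05 were counted with adjustment over all genes and adjusted over the list alone. Camera in limma compared each list with the other genes at a preset correlation of 0.01, and again with an estimated correlation, under which none of the calls held. Fry asked whether the genes of a list move, on balance, one way. Adjusted p-values of lists are over the lists of a comparison.

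Genes are named by a fixed rule. Gne is named in every comparison. In each comparison within a muscle up to 8 genes with the highest and 8 with the lowest fold change were eligible if they passed 0.05, bore no predicted-gene name, averaged at least 1 CPM and had CPM ranges that did not overlap between the groups. In each list up to 4 members past 0.05 with the smallest p were eligible, and where fewer than 2 passed, up to 2 more as values. The rule further takes up to 15 genes changed the same way in all 3 muscles, up to 6 genes with the smallest p in each test between muscles, and up to 5 higher and 5 lower genes in each comparison of wild-type muscles. The text names part of these.

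The procedure was tested on simulated data in which 100 genes changed 2-fold and 100 changed 4-fold among all genes tested. For sick knock-in against wild type it recovered 18 of the 2-fold and 73 of the 4-fold changes among 13943 genes in gastrocnemius, 39 and 70 among 13566 in quadriceps and 39 and 71 among 14276 in tibialis. For healthy knock-in against wild type it recovered 18 and 63 among 13925 genes, 42 and 79 among 13550 and 40 and 68 among 14269. For sick against healthy knock-in it recovered 15 and 54 among 13931 genes, 33 and 70 among 13578 and 31 and 68 among 14212. Between 1 and 6 unchanged genes were called per run. With no gene changed, 0 genes were called, except 1 for healthy knock-in against wild type in quadriceps. Relative log expression (RLE) factors, no filter on low counts, only the 2 groups compared, all 32 libraries in 1 model, a replicate block and leaving out each library in turn were tried as alternatives. Limma-trend on log2 of scaled counts plus 1, models without the sick replicate 2 or wild-type replicate 4 libraries of every muscle, list tests without quadriceps healthy replicate 4, and models without genes over 10 times higher in wild-type tibialis were added after the data were seen. Correlations of fold changes that share libraries were compared with 20 simulations of unchanged groups and with 6 splits of the wild-type libraries.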

Results

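Total RNA was sequenced from the gastrocnemius, quadriceps and tibialis, 3 muscles of the hind leg, of male mice aged up to 3 months. The mice were wild type or carried M743T on both alleles of Gne as a knock-in. Gne encodes the bifunctional key enzyme of sialic acid synthesis, and M743T is a variant found in patients with GNE myopathy, a recessive muscle disease. The submitters divided the knock-in mice into healthy and sick animals, and the signs of sickness are not given in the sources used here. The 32 libraries form 9 groups. The gastrocnemius gave 4 wild-type, 3 healthy knock-in and 3 sick knock-in libraries, and the quadriceps and the tibialis each gave 4, 4 and 3. Total counts per library ran from 7685164 to 42588233. Mitochondrial genome genes took 10.1 ± 1.82, 9.57 ± 2.04 and 7.36 ± 3.21% of the counts in wild-type, healthy and sick gastrocnemius (mean ± SD). In the same order they took 8.12 ± 1.81, 9.53 ± 2.34 and 6.01 ± 1.06% in quadriceps and 14.3 ± 0.892, 12.5 ± 1.52 and 10.9 ± 2.31% in tibialis.

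The targeted gene, Gne (ENSMUSG00000028479; GRCm38 chromosome 4, 44034075 to 44084177, minus strand), was read in every library at 7.35 to 14.3 CPM, which are counts scaled to a common library total. The wild-type gastrocnemius libraries held 10.3, 11.2, 9.92 and 9.25 (mean 10.2 ± 0.809, SD, n = 4) CPM of Gne, the healthy knock-in libraries 10.6, 10.6 and 10.3 (mean 10.5 ± 0.195, SD, n = 3) and the sick knock-in libraries 11.2, 11.2 and 7.35 (mean 9.93 ± 2.24, SD, n = 3). In quadriceps the wild-type libraries held 9.10, 9.75, 9.78 and 8.42 (mean 9.26 ± 0.645, SD, n = 4), the healthy knock-in libraries 9.26, 9.29, 10.7 and 14.3 (mean 10.9 ± 2.39, SD, n = 4) and the sick knock-in libraries 9.38, 9.85 and 10.8 (mean 10 ± 0.739, SD, n = 3). In tibialis the wild-type libraries held 10.8, 9.95, 9.85 and 11.1 (mean 10.4 ± 0.611, SD, n = 4), the healthy knock-in libraries 9.62, 9.39, 11.1 and 10.3 (mean 10.1 ± 0.791, SD, n = 4) and the sick knock-in libraries 10.3, 9.73 and 9.20 (mean 9.74 ± 0.548, SD, n = 3). The log2 fold change of Gne between sick knock-in and wild type was -0.02 ± 0.18, 0.11 ± 0.16 and -0.11 ± 0.14 (adjusted p = 0.958, 0.657 and 0.621) in gastrocnemius, quadriceps and tibialis (estimate ± SE, limma). Between healthy knock-in and wild type it was 0.03 ± 0.18, 0.20 ± 0.14 and -0.05 ± 0.13 (adjusted p = 0.958, 0.999 and 0.999). An amino acid change need not alter the transcript level, so these values do not check the labels.

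The comparison of sick knock-in with wild-type muscle addresses what accompanies sickness in the mutant mice. Sesn1, a stress-induced inhibitor of mTORC1 signalling, rose in all 3 muscles, with log2 fold changes of 3.35 ± 0.33, 2.98 ± 0.42 and 3.22 ± 0.54 in gastrocnemius, quadriceps and tibialis (estimate ± SE, 3 sick and 4 wild-type libraries per muscle). Values for the 3 muscles are given in this order throughout. Stc2, the gene of a secreted stanniocalcin, rose by 3.93 ± 0.55, 3.17 ± 0.45 and 3.47 ± 0.52, Ctxn3 by 4.44 ± 0.49, 5.06 ± 0.93 and 3.95 ± 0.65 and Gnmt, glycine N-methyltransferase, by 3.78 ± 0.51, 4.45 ± 0.76 and 3.28 ± 0.81. Nrep, a neuronal regeneration related gene, changed by -4.07 ± 0.58, -3.66 ± 0.57 and -4.12 ± 0.61, and Dupd1, a muscle dual-specificity phosphatase, by -3.83 ± 0.50, -3.20 ± 0.46 and -3.32 ± 0.48. The limma adjusted p was 0.000971, 0.00593 and 0.00551 for Sesn1, 0.00400, 0.00593 and 0.00357 for Stc2, 0.00154, 0.0113 and 0.00526 for Ctxn3, 0.00283, 0.0101 and 0.0211 for Gnmt, 0.00402, 0.00970 and 0.00325 for Nrep and 0.00280, 0.00598 and 0.00257 for Dupd1. Without sick knock-in replicate 2 the quadriceps changes of Ctxn3 and Gnmt did not pass (adjusted p = 0.0577 and 0.0517). Without wild-type replicate 1 the tibialis change of Gnmt did not (adjusted p = 0.0525).

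**Figure D1:**
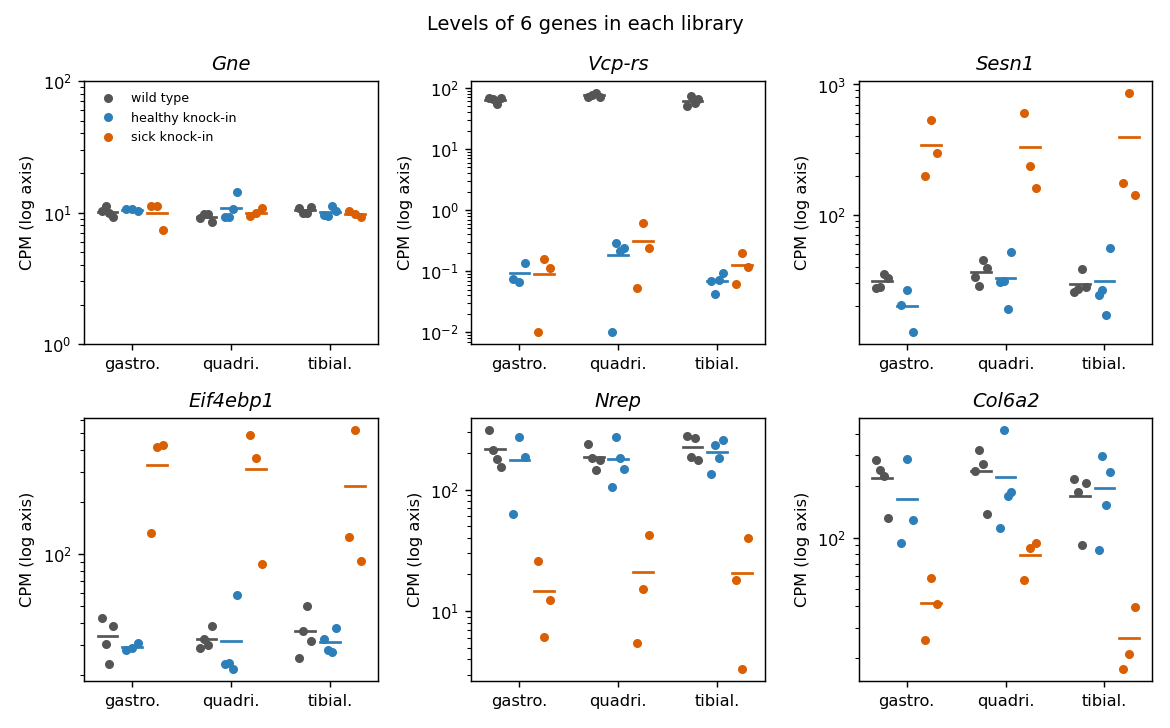
Level of 6 genes in each library, in CPM on a log axis (points; values under 0.01 are drawn at 0.01), with the mean of each group (line), by muscle and state. Gne lies between 7.35 and 14.3 CPM in every library, while Vcp-rs is near 0 in both knock-in states, and Sesn1 and Eif4ebp1 are higher and Nrep and Col6a2 lower in the sick knock-in groups.

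At an adjusted p under 0.05, 2087 of 14155 genes changed in sick gastrocnemius (1164 higher, 923 lower), 2488 of 13799 in quadriceps (1455 higher, 1033 lower) and 2621 of 14520 in tibialis (1226 higher, 1395 lower). CPM ranges of the sick and wild-type libraries did not overlap for 27.2%, 30.4% and 31% of the genes, where chance gives 5.71%. Of 13562 genes tested in every muscle, 477 were higher and 301 lower in all 3, where independent lists would share 10.6 and 6.33. Fold changes correlated across genes, which are not independent, with r = 0.868 (gastrocnemius, quadriceps), 0.826 (gastrocnemius, tibialis) and 0.717 (quadriceps, tibialis). The authors' deposited table lists 3102, 2360 and 3824 genes at an adjusted p under 0.05, of which 1922, 1881 and 2455 also passed here, each in the same direction. The gastrocnemius count was 905 without wild-type replicate 2, 1267 without wild-type replicate 3 and 561 without sick replicate 2. Without sick replicate 3, 704 of the 2087 genes and 39 others passed. The quadriceps count was 852, 1026 and 738 without wild-type replicates 1, 2 and 3, and 83, 692 and 4249 without sick replicates 2, 3 and 4. In tibialis it was 1535 and 1452 without wild-type replicates 1 and 2, and 1688 and 957 without sick replicates 1 and 2. Fits of the sick and wild-type libraries alone gave 1231 genes in gastrocnemius and 1236 in tibialis, and a fit of all 32 libraries 3280 in gastrocnemius. Without sick replicate 2 in every muscle, 37 genes changed the same way in all 3.

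**Figure D2:**
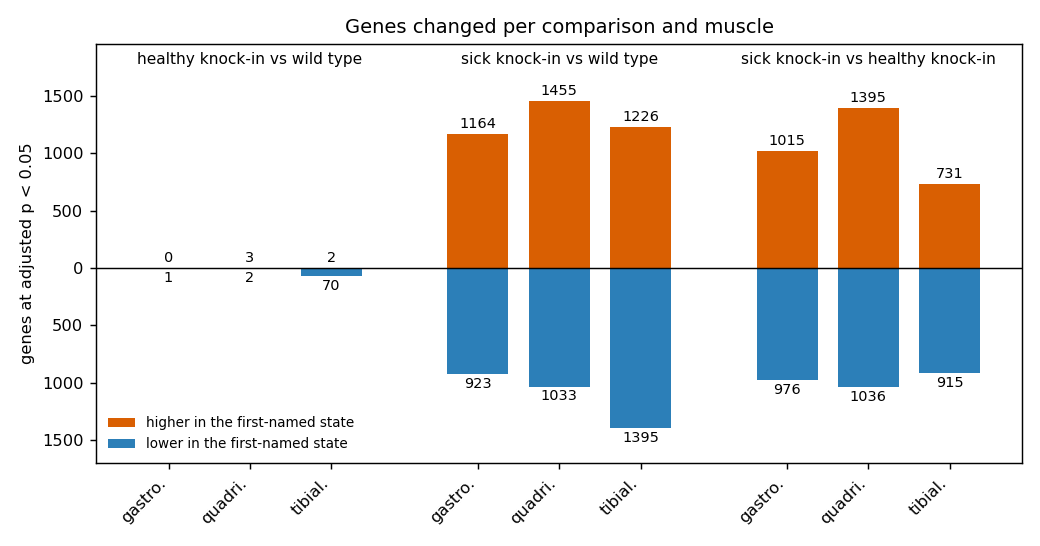
Number of genes at an adjusted p under 0.05 in each comparison and muscle (limma-voom), with genes higher in the first-named state above 0 and genes lower below 0. The healthy knock-in groups differ from wild type by 1, 5 and 72 genes, and the sick knock-in groups by 2087, 2488 and 2621.

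Of the genes of muscle atrophy, such as ubiquitin ligases and proteolysis regulators, most rose in each of the sick muscles. Of 24 measured, 16, 17 and 13 rose and 0, 1 and 0 fell (20, 19 and 17 rose and 0, 1 and 0 fell adjusted over the list alone). For atrophy genes, camera gave adjusted p = 6.52e-11, 2.8e-08 and 5.11e-08 (adjusted p = 0.516, 0.605 and 0.688 with an estimated correlation). Eif4ebp1, a repressor of translation initiation, rose by 3.14 ± 0.36, 2.97 ± 0.51 and 2.38 ± 0.46 (adjusted p = 0.00154, 0.0101 and 0.00936), and Fbxo31, an F-box gene, by 1.82 ± 0.24 and 1.86 ± 0.37 in gastrocnemius and tibialis. In tibialis Fbxo32, which encodes atrogin-1, rose by 2.80 ± 0.58 and Mstn, the gene of the growth inhibitor myostatin, by 1.72 ± 0.27. Ctsl, a lysosomal protease gene, rose by 2.31 ± 0.33 in gastrocnemius, and Foxo3 by 1.39 ± 0.25 in quadriceps. The member that fell in quadriceps was Fbxo40, a muscle F-box gene, at -0.58 ± 0.17, which falls outside the rule for named genes and was chosen after its value was seen. Of 18 glucocorticoid-responsive genes, 11, 10 and 9 rose and none fell (14, 14 and 11 rose and none fell adjusted over the list alone). For glucocorticoid-responsive genes, camera gave adjusted p = 2.19e-07, 7.1e-07 and 1.47e-05 (adjusted p = 0.516, 0.605 and 0.688 with an estimated correlation). Klf15 rose by 2.22 ± 0.35 and the metallothionein gene Mt1 by 3.36 ± 0.49 in gastrocnemius, and Nfkbia, an inhibitor of NF-kappa-B, by 1.40 ± 0.27, 1.88 ± 0.31 and 1.41 ± 0.27 in the 3 muscles. Of 29 lysosome and autophagy genes, 8, 11 and 4 rose and none fell (12, 14 and 0 rose and none fell adjusted over the list alone), with Map1lc3b at 1.62 ± 0.29 in gastrocnemius. For lysosome and autophagy genes, camera gave adjusted p = 0.000518, 9.98e-05 and 0.0332 (adjusted p = 0.568, 0.623 and 0.80 with an estimated correlation). Of 18 p53 targets, 5, 5 and 4 rose and 1, 2 and 2 fell (6, 9 and 5 rose and 3, 5 and 2 fell adjusted over the list alone), with the cell-cycle inhibitor Cdkn1a at 3.73 ± 0.60 in quadriceps. For p53 targets, camera gave adjusted p = 0.0289, 0.0865 and 0.0947 (adjusted p = 0.516, 0.605 and 0.688 with an estimated correlation). Of 16 genes of the growth hormone and insulin-like growth factor axis, 6, 4 and 6 rose and 2, 1 and 2 fell (8, 6 and 7 rose and 2, 3 and 2 fell adjusted over the list alone; camera adjusted p = 0.0832, 0.203 and 0.0617). Igf1r, the receptor, rose by 1.78 ± 0.22, 1.40 ± 0.30 and 1.81 ± 0.36, Igfbp3 by 2.78 ± 0.35 in gastrocnemius and Pik3r1 by 1.99 ± 0.35 in tibialis, while Igfbp5 was lower in gastrocnemius, at -2.61 ± 0.46. The quadriceps changes of Eif4ebp1, Foxo3, Nfkbia, Cdkn1a and Igf1r did not pass without sick knock-in replicate 2 (adjusted p = 0.0517 to 0.0598), nor did Fbxo32 in tibialis with no filter on low counts (adjusted p = 0.0595).

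**Figure D3:**
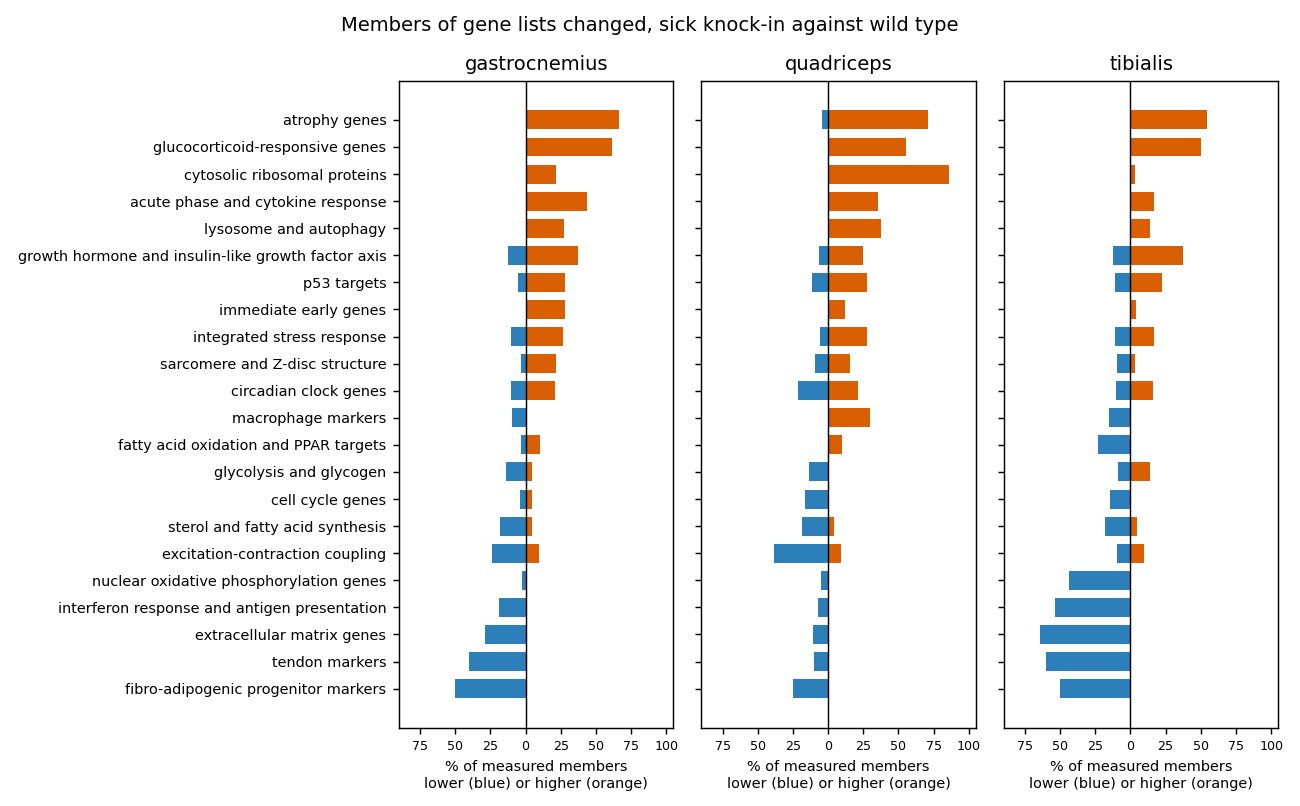
Share of the measured members of each gene list that were higher (orange, right) or lower (blue, left) in sick knock-in than in wild-type muscle at an adjusted p under 0.05, by muscle, for the 22 lists with at least 10 such members summed over the muscles. Atrophy and glucocorticoid-responsive genes extend to the right in every muscle, and extracellular matrix genes to the left.

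Of 28 extracellular matrix genes, none rose and 8, 3 and 18 fell (none rose and 9, 1 and 22 fell adjusted over the list alone). For extracellular matrix genes, camera gave adjusted p = 0.000441, 0.126 and 5.11e-08 (adjusted p = 0.710, 0.781 and 0.688 with an estimated correlation). Serpinh1, the collagen chaperone, changed by -2.30 ± 0.34, -1.83 ± 0.39 and -2.09 ± 0.35, Col6a2 by -2.42 ± 0.42 and -2.75 ± 0.44 in gastrocnemius and tibialis, and the fibrillar collagen genes Col3a1 and Col1a2 by -3.51 ± 0.61 and -3.03 ± 0.55 in tibialis. Of 12 markers of fibro-adipogenic progenitors, the mesenchymal cells between fibres, none rose and 6, 3 and 6 fell (none rose and 7, 5 and 6 fell adjusted over the list alone). For fibro-adipogenic progenitor markers, camera gave adjusted p = 0.000518, 0.0617 and 0.000102 (adjusted p = 0.568, 0.638 and 0.688 with an estimated correlation). Smoc2 changed by -1.45 ± 0.26, -1.39 ± 0.28 and -1.98 ± 0.21, Col15a1 by -2.59 ± 0.52, -2.25 ± 0.41 and -2.62 ± 0.46, Cd34 by -1.29 ± 0.20 and -1.22 ± 0.24 in gastrocnemius and tibialis, and Lum by -3.38 ± 0.41 in tibialis. Of 10 tendon markers, none rose and 4, 1 and 6 fell (none rose and 8, 3 and 8 fell adjusted over the list alone), with the proteoglycan gene Kera at -5.89 ± 1.06 in gastrocnemius. For tendon markers, camera gave adjusted p = 0.000518, 0.0330 and 0.000847 (adjusted p = 0.624, 0.688 and 0.688 with an estimated correlation). Of the interferon response and antigen presentation genes (26, 28 and 26 measured), none rose and 5, 2 and 14 fell (none rose and 5, 2 and 20 fell adjusted over the list alone). For interferon response and antigen presentation genes, camera gave adjusted p = 2.68e-05, 0.0365 and 1.79e-07 (adjusted p = 0.568, 0.752 and 0.688 with an estimated correlation). Igtp, an interferon-induced GTPase gene, changed by -1.64 ± 0.32 in quadriceps. Of 20 macrophage markers, 0, 6 and 0 rose and 2, 0 and 3 fell (0, 10 and 0 rose and 2, 0 and 3 fell adjusted over the list alone). For macrophage markers, camera gave adjusted p = 0.481, 0.00545 and 0.0490 (adjusted p = 0.857, 0.605 and 0.801 with an estimated correlation). In tibialis H2-Aa changed by -2.28 ± 0.40 and Cd74 by -2.18 ± 0.43, whereas in quadriceps Lyz2, a myeloid lysozyme, rose by 1.20 ± 0.26. Without sick knock-in replicate 2 the quadriceps changes of Serpinh1, Smoc2, Col15a1, Igtp and Lyz2 did not pass (adjusted p = 0.0551 to 0.0974), and that of Lyz2 did not without sick replicate 3 or in a fit of all 32 libraries (adjusted p = 0.0598 and 0.0592). With no filter on low counts Col3a1 and Col1a2 did not pass in tibialis (adjusted p = 0.0511 and 0.0609).

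Of 16 endothelial markers, 0, 0 and 1 rose and 0, 1 and 1 fell (0, 0 and 1 rose and 0, 1 and 1 fell adjusted over the list alone; camera adjusted p = 0.393, 0.0956 and 0.291). Of 12 smooth muscle and pericyte markers, 1, 1 and 0 rose and 1, 1 and 1 fell (1, 1 and 0 rose and 1, 1 and 1 fell adjusted over the list alone; camera adjusted p = 0.272, 0.318 and 0.329). Among Schwann cell and nerve markers (14, 13 and 14 measured), none rose and 0, 0 and 2 fell (none rose or fell adjusted over the list alone). For Schwann cell and nerve markers, camera gave adjusted p = 0.341, 1.0 and 0.0449 (adjusted p = 0.857, 1.0 and 0.80 with an estimated correlation). Of 15, 14 and 14 adipocyte markers, none rose and 0, 1 and 0 fell (none rose or fell adjusted over the list alone; camera adjusted p = 0.731, 0.437 and 0.329). Of 11, 10 and 11 satellite cell markers, 1, 1 and 1 rose and 1, 1 and 0 fell (1, 1 and 1 rose and 1, 2 and 0 fell adjusted over the list alone; camera adjusted p = 0.393, 0.279 and 0.283), among them Cdh15, the gene of M-cadherin, which rose by 1.02 ± 0.16 in gastrocnemius. Of 7, 6 and 6 erythrocyte markers, 4, 1 and 0 rose and 1, 1 and 0 fell (6, 4 and 0 rose and 1, 1 and 0 fell adjusted over the list alone), with the anion exchanger gene Slc4a1 at 3.71 ± 0.83 in gastrocnemius. For erythrocyte markers, camera gave adjusted p = 0.0110, 0.148 and 0.678 (adjusted p = 0.568, 0.638 and 0.886 with an estimated correlation). Of 3, 4 and 3 neutrophil markers, 2, 0 and 0 rose and none fell (2, 0 and 0 rose and none fell adjusted over the list alone; camera adjusted p = 0.169, 0.409 and 0.678). No lymphocyte marker had enough counts to be measured.

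Of 28 cytosolic ribosomal protein genes, 6, 24 and 1 rose and none fell (12, 27 and 0 rose and none fell adjusted over the list alone), with Rps6 at 0.68 ± 0.12 and Rpl10a at 0.79 ± 0.15 in quadriceps. For cytosolic ribosomal proteins, camera gave adjusted p = 3.59e-07, 6.03e-13 and 8.45e-05 (adjusted p = 0.624, 0.605 and 0.80 with an estimated correlation). Of 39 nuclear genes of oxidative phosphorylation, none rose and 1, 2 and 17 fell (none rose and 1, 2 and 29 fell adjusted over the list alone). For nuclear oxidative phosphorylation genes, camera gave adjusted p = 3.08e-05, 0.00294 and 1.27e-09 (adjusted p = 0.710, 0.752 and 0.688 with an estimated correlation). Cycs, cytochrome c, changed by -1.08 ± 0.24, -0.68 ± 0.13 and -1.22 ± 0.23 (adjusted p = 0.0169, 0.0109 and 0.00874), and Uqcrc1, a subunit of complex III, by -0.90 ± 0.21 in tibialis. Of 12 mitochondrial genome genes, none rose and 1, 2 and 1 fell (none rose and 1, 2 and 0 fell adjusted over the list alone). For mitochondrial genome genes, camera gave adjusted p = 0.0168, 0.00294 and 0.0226 (adjusted p = 0.710, 0.638 and 0.80 with an estimated correlation). These genes took 7.36, 6.01 and 10.9% of counts in the sick libraries and 10.1, 8.12 and 14.3% in the wild-type libraries. Among 30 genes of fatty acid oxidation, 3, 3 and 0 rose and 1, 0 and 7 fell (4, 2 and 0 rose and 1, 0 and 9 fell adjusted over the list alone). For the fatty acid oxidation list, camera gave adjusted p = 0.466, 0.202 and 0.0176 (adjusted p = 0.857, 0.813 and 0.80 with an estimated correlation). Among 22 genes of glycolysis and glycogen, 1, 0 and 3 rose and 3, 3 and 2 fell (2, 0 and 3 rose and 7, 3 and 2 fell adjusted over the list alone; camera adjusted p = 0.152, 0.277 and 0.678). Among 22 genes of sterol and fatty acid synthesis, 1, 1 and 1 rose and 4, 4 and 4 fell (2, 1 and 1 rose and 5, 4 and 4 fell adjusted over the list alone; camera adjusted p = 0.136, 0.242 and 0.605), with the squalene synthase gene Fdft1 higher in gastrocnemius at 1.54 ± 0.20 and Dhcr7, the last step of cholesterol synthesis, lower in tibialis at -1.66 ± 0.30. Without sick knock-in replicate 2, Rps6, Rpl10a and Cycs did not pass in quadriceps (adjusted p = 0.055 to 0.0559), nor did Cycs in gastrocnemius or Uqcrc1 in tibialis (adjusted p = 0.0565 and 0.0618). In a fit of the sick and wild-type libraries alone Uqcrc1 did not pass either (adjusted p = 0.0565).

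Contractile genes moved in both directions. Ankrd1, a titin-binding stress gene, rose by 3.50 ± 0.36 and 3.05 ± 0.38 in gastrocnemius and quadriceps (adjusted p = 0.00113 and 0.00563), and its value in tibialis was -1.25 ± 0.81 (adjusted p = 0.284). Sln, the gene of the calcium pump inhibitor sarcolipin, rose by 4.38 ± 0.65 in gastrocnemius. In tibialis the fast-fibre gene Actn3 rose by 1.36 ± 0.24 and the small heat shock gene Cryab changed by -2.44 ± 0.50. Of 15 fast fibre genes, 0, 0 and 2 rose and 1, 1 and 2 fell (0, 0 and 3 rose and 1, 1 and 3 fell adjusted over the list alone; camera adjusted p = 0.272, 0.234 and 0.987). Of 14 slow fibre genes, 1, 4 and 0 rose and 0, 0 and 2 fell (1, 6 and 1 rose and 0, 0 and 2 fell adjusted over the list alone). For slow fibre contractile genes, camera gave adjusted p = 0.0201, 0.00156 and 0.219 (adjusted p = 0.710, 0.638 and 0.826 with an estimated correlation). Of 32 genes of the sarcomere and Z-disc, 7, 5 and 1 rose and 1, 3 and 3 fell (7, 6 and 1 rose and 1, 6 and 3 fell adjusted over the list alone; camera adjusted p = 0.125, 1.0 and 0.283), with the Z-disc gene Myoz3 at -2.87 ± 0.49 in gastrocnemius. Among 21 genes of excitation-contraction coupling, 2, 2 and 2 rose and 5, 8 and 2 fell (2, 2 and 3 rose and 5, 10 and 2 fell adjusted over the list alone). For excitation-contraction coupling genes, camera gave adjusted p = 0.175, 0.00109 and 0.808 (adjusted p = 0.753, 0.638 and 0.949 with an estimated correlation). Of 12 embryonic and regenerating fibre genes, 1, 1 and 1 rose and none fell (1, 0 and 1 rose and none fell adjusted over the list alone; camera adjusted p = 0.272, 0.335 and 0.436). Of 19 genes of the neuromuscular junction and denervation, 1, 1 and 0 rose and 0, 2 and 0 fell (0, 4 and 0 rose and 0, 2 and 0 fell adjusted over the list alone; camera adjusted p = 0.393, 0.840 and 0.678). Of 22 genes of the dystrophin complex and its glycosylation, 0, 1 and 2 rose and 0, 4 and 0 fell (0, 1 and 2 rose and 0, 4 and 0 fell adjusted over the list alone; camera adjusted p = 0.617, 0.287 and 0.340), with the sarcoglycan gene Sgcd at -1.03 ± 0.20 in quadriceps. The change of Sgcd did not pass without sick knock-in replicate 2 (adjusted p = 0.0696), nor did that of Cryab with no filter on low counts (adjusted p = 0.0523).

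Of 25 genes of the sialic acid pathway, in which Gne acts, 0, 1 and 1 rose and 4, 1 and 1 fell (none rose and 5, 0 and 1 fell adjusted over the list alone; camera adjusted p = 0.0533, 0.277 and 0.0892). St8sia5, a sialyltransferase of gangliosides, changed by -1.59 ± 0.27 in gastrocnemius, and St3gal5, the GM3 synthase gene, by -1.31 ± 0.15 in tibialis. Tested on its own with limma's fry, the list lay lower on balance in gastrocnemius and tibialis (adjusted p = 0.0136 and 0.0102), and in quadriceps the adjusted p was 0.202. Of 19, 18 and 18 genes of the integrated stress response, 5, 5 and 3 rose and 2, 1 and 2 fell (6, 7 and 4 rose and 2, 1 and 4 fell adjusted over the list alone; camera adjusted p = 0.198, 0.126 and 0.771), with Atf3 at 2.77 ± 0.42 and Atf4 at 1.30 ± 0.23 in gastrocnemius. Among 17 endoplasmic reticulum chaperones, 0, 2 and 0 rose and 5, 0 and 2 fell (2, 2 and 0 rose and 6, 0 and 0 fell adjusted over the list alone; camera adjusted p = 0.198, 0.492 and 0.605). Of 16 cytosolic heat shock genes, 0, 1 and 0 rose and 2, 1 and 5 fell (0, 0 and 1 rose and 2, 0 and 7 fell adjusted over the list alone). For cytosolic heat shock genes, camera gave adjusted p = 0.685, 0.502 and 0.00808 (adjusted p = 0.891, 0.868 and 0.688 with an estimated correlation). Of 25 immediate early genes, 7, 3 and 1 rose and none fell (7, 7 and 0 rose and none fell adjusted over the list alone). For immediate early genes, camera gave adjusted p = 4.34e-05, 0.000150 and 0.0116 (adjusted p = 0.568, 0.638 and 0.80 with an estimated correlation). Of 16, 17 and 18 genes of the acute phase and cytokine response, 7, 6 and 3 rose and none fell (8, 6 and 3 rose and none fell adjusted over the list alone), with Il6ra, the receptor of interleukin 6, at 3.41 ± 0.40 in gastrocnemius. For acute phase and cytokine response genes, camera gave adjusted p = 0.00520, 0.00294 and 0.0298 (adjusted p = 0.592, 0.638 and 0.80 with an estimated correlation). Of 19 circadian clock genes, 4, 4 and 3 rose and 2, 4 and 2 fell (5, 6 and 5 rose and 2, 4 and 2 fell adjusted over the list alone; camera adjusted p = 0.152, 0.5 and 0.108), with Cry2 at 2.20 ± 0.29 in gastrocnemius and Rora at 2.02 ± 0.37 in tibialis. Among cell cycle genes (23, 24 and 28 measured), 1, 0 and 0 rose and 1, 4 and 4 fell (0, 2 and 0 rose and 0, 10 and 4 fell adjusted over the list alone). For cell cycle genes, camera gave adjusted p = 0.393, 0.00294 and 0.0176 (adjusted p = 0.801, 0.605 and 0.688 with an estimated correlation).

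The comparison of healthy knock-in with wild-type muscle asks what the mutation goes with in mice without sickness. Vcp-rs, a copy of the chaperone gene Vcp on chromosome X (ENSMUSG00000083327, 104345829 to 104348234), was the gene changed in all 3 muscles. It was read at 64.4 ± 6.69, 75.2 ± 5.08 and 61.1 ± 9.40 CPM in wild type, and in the healthy knock-in its summed counts were 4, 12 and 5, with log2 fold changes of -9.04 ± 0.55, -8.56 ± 0.52 and -9.32 ± 0.45 (adjusted p = 3.66e-05, 3.04e-05 and 9.79e-07). Against wild type the sick knock-in values were -9.28 ± 0.55, -8.42 ± 0.59 and -8.68 ± 0.46 (adjusted p = 2.75e-05, 7.71e-05 and 3.27e-06). Counts of Vcp-rs are uncertain because its sequence nearly repeats that of Vcp. Sesn1 did not pass in the healthy mice, at -0.70 ± 0.31, -0.26 ± 0.39 and -0.04 ± 0.48 (adjusted p = 0.647, 0.999 and 0.999). In quadriceps 5 genes passed, which besides Vcp-rs were Hint2, a nucleotide hydrolase, at 1.55 ± 0.21 (adjusted p = 0.0413), Galt of galactose metabolism at 0.97 ± 0.14 (adjusted p = 0.0469), Gm1840 at 4.91 ± 0.64 (adjusted p = 0.0413) and Gm13305 at -5.04 ± 0.51 (adjusted p = 0.00340). Gm1840 and Gm13305 fall outside the rule for named genes and were chosen after their values were seen. Hint2 (43654227 onward), Galt (41755228 onward) and Gm13305 (42158842 to 42168603) lie on chromosome 4, as Gne does.

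In tibialis 72 genes passed between healthy knock-in and wild type, 2 higher and 70 lower, and 28 of the 70 were genes over 10 times higher in wild-type tibialis than in both other wild-type muscles. The count was 36 with such genes left out and 123 with no filter on low counts. The 28 include genes known from the kidney. Kap, the kidney androgen-regulated gene, was at 37.1 ± 4.54 CPM in wild type and 0.429 CPM in the healthy knock-in (35 counts over 4 libraries), a log2 fold change of -6.98 ± 0.64 (adjusted p = 0.000130). Slc34a1, a renal phosphate transporter, changed by -6.61 ± 0.53 (adjusted p = 4.97e-05) and Lrp2, the gene of megalin, by -6.49 ± 0.60 (adjusted p = 0.000130). Umod, the gene of uromodulin, and Mep1a, a meprin gene, had no read in any healthy knock-in tibialis, at least 81.6-fold and 97.4-fold lower than the wild-type means of 3.34 and 3.99 CPM when set against 3 counts over the group (adjusted p = 6.91e-06 and 1.17e-05). Gprc5c, an orphan receptor, rose by 0.89 ± 0.16 (adjusted p = 0.0229). In sick tibialis Slc34a1 and Umod had no read either, at least 203-fold and 65.4-fold below wild type (adjusted p = 2.94e-05 and 2.63e-05), and Kap had 2 counts over 3 libraries. Summed over 24 kidney markers, those of a list of 26 made after this was seen that had at least 10 counts there, wild-type tibialis libraries held 50.7 to 74.6 CPM and no other library more than 23.6 CPM, the value of gastrocnemius healthy replicate 2.

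**Figure D4:**
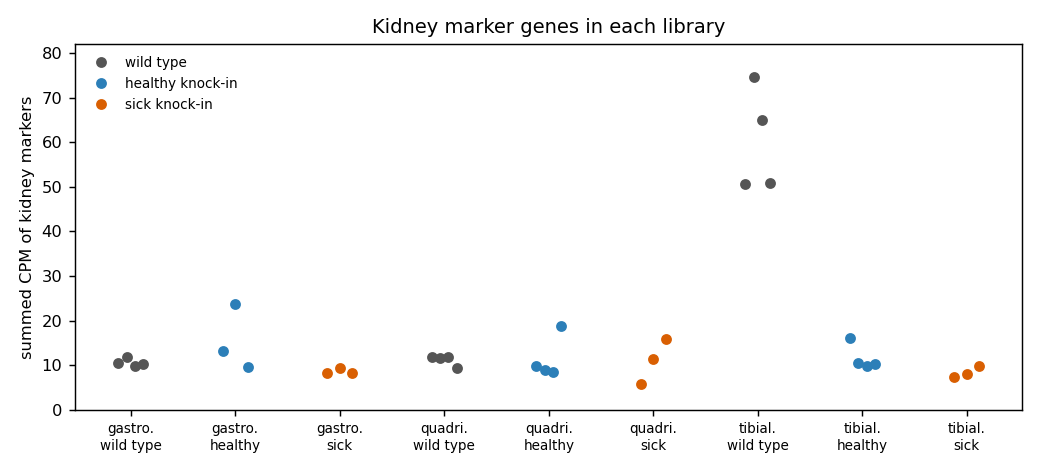
Summed CPM of 24 kidney marker genes in each library (points), by muscle and state. The 4 wild-type tibialis libraries lie between 50.7 and 74.6 CPM, and every other library lies at or below 23.6 CPM.

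In gastrocnemius 1 gene passed between healthy knock-in and wild type, Vcp-rs, and 1083 had an unadjusted p under 0.05, against 637 in quadriceps and 716 in tibialis. No member of any of the 39 lists passed over all genes, although adjusted over the list alone 3 macrophage markers and 3 genes of sterol and fatty acid synthesis were higher in quadriceps. As a list, endothelial markers lay lower in the 3 muscles (camera adjusted p = 1.41e-05, 5.76e-07 and 1.05e-06; adjusted p = 0.898, 0.150 and 0.403 with an estimated correlation). Nuclear oxidative phosphorylation genes lay lower in gastrocnemius and tibialis (camera adjusted p = 1.55e-07 and 3.68e-20; adjusted p = 0.898 and 0.843 with an estimated correlation). In quadriceps they were not called (camera adjusted p = 0.444), but without healthy replicate 4 they lay higher (camera adjusted p = 0.0325; adjusted p = 0.746 with an estimated correlation). Macrophage markers lay higher in quadriceps and tibialis (camera adjusted p = 9.04e-13 and 0.0234; adjusted p = 0.0744 and 0.887 with an estimated correlation), though not in gastrocnemius (camera adjusted p = 0.296). So did genes of sterol and fatty acid synthesis (camera adjusted p = 3.09e-09 and 3.29e-06; adjusted p = 0.150 and 0.403 with an estimated correlation), but adipocyte markers were at 8.80 on the log2(CPM + 1) scale in quadriceps healthy replicate 4, against 4.30 to 4.80 in the other 3, and the fatty acid synthase gene Fasn was at 1050 ± 1973 CPM in healthy and 67.6 ± 13.5 CPM in wild-type quadriceps. Without this library, a setting chosen after the data were seen, camera gave this list in quadriceps an adjusted p = 0.000457 (adjusted p = 0.465 with an estimated correlation). In total 11, 15 and 8 lists were called with the preset correlation and 0 with an estimated one. The authors' deposited table lists 18, 14 and 38 genes, of which 1, 3 and 33 passed here. The gastrocnemius count was 3 without wild-type replicate 2, 9 without wild-type replicate 4 and 2 without healthy replicate 3. In quadriceps it was 2 without wild-type replicate 1, 2 or 3, 13 without wild-type replicate 4, 3 without healthy replicate 1 or 4 and 2 without healthy replicate 3. Hint2, Galt and Gm1840 each lost the call without wild-type replicate 1, 2 or 3 or healthy replicate 1 or 3 (adjusted p = 0.104 to 0.419), Hint2 and Gm1840 also without healthy replicate 4 (both 0.111), Galt and Gm1840 without healthy replicate 2 (0.0576 and 0.064) and Galt without wild-type replicate 4 (0.0656). Gprc5c in tibialis lost it without wild-type replicate 1, 2 or 3 or healthy replicate 2 or 3 (adjusted p = 0.0766 to 0.104). The gastrocnemius count was 7 with no filter on low counts, and both counts were 2 by limma-trend and 10 and 9 in a fit of all 32 libraries. In a fit of the healthy and wild-type libraries alone the quadriceps count was 2 and none of these 4 genes passed (adjusted p = 0.0531 to 0.155). By limma-trend Hint2, Galt and Gm1840 did not pass (adjusted p = 0.0831, 0.0942 and 0.561). With no filter on low counts Galt and Gm1840 did not (adjusted p = 0.134 and 0.182), and in a fit of all 32 libraries Galt did not (adjusted p = 0.318).

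Sick and healthy knock-in mice share the mutation, and their comparison asks what goes with sickness alone. Cited4, a transcriptional coactivator gene, was lower in the sick mice in all 3 muscles, at -5.08 ± 0.78, -4.43 ± 0.65 and -3.69 ± 0.52 (adjusted p = 0.00430, 0.00547 and 0.00863), and so were Nrep (-3.58 ± 0.59, -3.54 ± 0.56 and -3.95 ± 0.61) and Dupd1 (-4.57 ± 0.52, -3.38 ± 0.46 and -3.63 ± 0.48). Sesn1 rose by 4.06 ± 0.35, 3.24 ± 0.43 and 3.26 ± 0.54 (adjusted p = 0.000930, 0.00464 and 0.0101), Stc2 by 4.04 ± 0.69, 2.99 ± 0.47 and 3.30 ± 0.52 and Eif4ebp1 by 3.33 ± 0.38, 3.15 ± 0.53 and 2.53 ± 0.46. Nmrk2, a muscle kinase of NAD synthesis, changed by -5.08 ± 0.59 and -4.27 ± 0.82 in gastrocnemius and tibialis. In gastrocnemius Amd1, the decarboxylase of polyamine synthesis, changed by -5.58 ± 0.62 and Egln3, a prolyl hydroxylase gene, by 4.61 ± 0.44. Counts of changed genes were 1991 (1015 higher, 976 lower), 2431 (1395 higher, 1036 lower) and 1646 (731 higher, 915 lower). In all 3 muscles, which may share mice, 328 were higher and 272 lower (5.29 and 4.71 for independent lists). CPM ranges did not overlap for 37.6%, 24.2% and 28.8% of genes, where chance gives 10%, 5.71% and 5.71%. The authors' deposited table lists 3073, 2581 and 3034 genes, of which 1875, 1926 and 1550 passed here. The gastrocnemius count was 962, 1152 and 728 without healthy replicates 1, 2 and 3, and 814 and 1043 without sick replicates 2 and 3. The quadriceps count was 1421 and 1054 without healthy replicates 2 and 3, and 287, 745 and 4096 without sick replicates 2, 3 and 4. In tibialis it was 924, 389, 788 and 797 without healthy replicates 1 to 4, and 302 and 266 without sick replicates 1 and 2. In a fit of the sick and healthy libraries alone the counts were 366 in quadriceps and 95 in tibialis, with 37 genes in all 3 muscles, and Sesn1, Stc2, Nrep, Nmrk2 and Eif4ebp1 did not pass in tibialis (adjusted p = 0.0515 to 0.0559), nor did Eif4ebp1 with no filter on low counts (adjusted p = 0.0577). With no filter on low counts 1458 and 1086 genes passed in quadriceps and tibialis, and in a fit of all 32 libraries 2951 did in tibialis. Without sick replicate 2 in every muscle, 64 genes changed the same way in all 3.

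In sick against healthy mutants, of 24 atrophy genes, 15, 15 and 8 rose and none fell (17, 18 and 17 rose and 1, 1 and 0 fell adjusted over the list alone), with Foxo3 at 1.53 ± 0.26 in quadriceps. For atrophy genes, camera gave adjusted p = 5.75e-10, 1.92e-08 and 2.51e-08 (adjusted p = 0.568, 0.618 and 0.528 with an estimated correlation). Of 18 glucocorticoid-responsive genes, 10, 8 and 6 rose and none fell (15, 14 and 10 rose and none fell adjusted over the list alone). For glucocorticoid-responsive genes, camera gave adjusted p = 1.69e-08, 4.1e-06 and 4.34e-05 (adjusted p = 0.568, 0.618 and 0.569 with an estimated correlation). Of 29 lysosome and autophagy genes, 8, 9 and 1 rose and 0, 1 and 0 fell (10, 11 and 0 rose and 1, 2 and 0 fell adjusted over the list alone), with Map1lc3b at 1.72 ± 0.30 and 1.58 ± 0.29 in gastrocnemius and quadriceps. For lysosome and autophagy genes, camera gave adjusted p = 0.000425, 0.00365 and 0.0705 (adjusted p = 0.619, 0.778 and 0.956 with an estimated correlation). Of 28 ribosomal protein genes, 7, 22 and 1 rose and none fell (24, 25 and 0 rose and none fell adjusted over the list alone). For cytosolic ribosomal proteins, camera gave adjusted p = 9.01e-09, 9.46e-12 and 6.71e-07 (adjusted p = 0.619, 0.618 and 0.528 with an estimated correlation). Of 28 extracellular matrix genes, 2, 0 and 0 rose and 4, 2 and 17 fell (2, 0 and 0 rose and 4, 1 and 20 fell adjusted over the list alone). For extracellular matrix genes, camera gave adjusted p = 0.232, 0.187 and 7.37e-10 (adjusted p = 0.895, 0.965 and 0.528 with an estimated correlation). In tibialis Col6a2 changed by -2.83 ± 0.44, Col1a2 by -3.27 ± 0.56, Lum by -3.00 ± 0.41 and Smoc2 by -1.86 ± 0.21; Col1a2 did not pass in a fit of the sick and healthy libraries alone or with no filter on low counts (adjusted p = 0.0515 and 0.0632). Of 26, 28 and 26 interferon genes, none rose and 1, 3 and 11 fell (none rose and 1, 3 and 19 fell adjusted over the list alone), with Igtp at -2.31 ± 0.42 and -2.45 ± 0.32 in gastrocnemius and quadriceps. For interferon response and antigen presentation genes, camera gave adjusted p = 0.00939, 0.000130 and 8.58e-09 (adjusted p = 0.640, 0.778 and 0.528 with an estimated correlation). Of 22 genes of sterol and fatty acid synthesis, 1, 1 and 1 rose and 5, 6 and 7 fell (1, 1 and 1 rose and 5, 10 and 10 fell adjusted over the list alone). For sterol and fatty acid synthesis genes, camera gave adjusted p = 0.0584, 0.000772 and 0.00633 (adjusted p = 0.640, 0.618 and 0.528 with an estimated correlation). Fdft1 was the exception that rose in gastrocnemius, at 1.66 ± 0.21. Of 30 fatty acid oxidation genes, 8, 3 and 1 rose and 0, 1 and 1 fell (8, 3 and 1 rose and 1, 0 and 1 fell adjusted over the list alone), with Mlycd, malonyl-CoA decarboxylase, at 1.33 ± 0.23 in gastrocnemius. For the fatty acid oxidation list, camera gave adjusted p = 0.000212, 0.888 and 0.915 (adjusted p = 0.619, 0.976 and 0.978 with an estimated correlation). In quadriceps Cycs changed by -0.75 ± 0.12 and Ndufs1, a complex I subunit, by -0.76 ± 0.14.

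Ankrd1 was higher in the sick than in the healthy mutants in gastrocnemius and quadriceps, at 4.10 ± 0.45 and 2.86 ± 0.40, as was Csrp3, the gene of the muscle LIM protein, in gastrocnemius at 5.01 ± 0.81, a change that did not pass with no filter on low counts (adjusted p = 0.0634). Myoz3 was lower in gastrocnemius, at -3.40 ± 0.51. Igf1r rose by 1.95 ± 0.25 and 1.71 ± 0.33 in gastrocnemius and quadriceps while Igf1 changed by -1.83 ± 0.38 in gastrocnemius. Of the sialic acid pathway, 0, 2 and 0 rose and 4, 1 and 2 fell (0, 1 and 0 rose and 4, 1 and 2 fell adjusted over the list alone; camera adjusted p = 0.0589, 0.228 and 0.0993), with St8sia5 at -1.74 ± 0.29 and St3gal6 at -1.18 ± 0.20 in gastrocnemius and St3gal5 at -0.97 ± 0.15 in tibialis. Of the clock genes, 3, 3 and 3 rose and 1, 1 and 1 fell (6, 4 and 10 rose and 2, 1 and 2 fell adjusted over the list alone), with Cry2 at 2.26 ± 0.31 and the repressor Bhlhe41 at -2.98 ± 0.54 in gastrocnemius. For circadian clock genes, camera gave adjusted p = 0.165, 0.140 and 0.0305 (adjusted p = 0.692, 0.778 and 0.555 with an estimated correlation). Of the integrated stress response, 5, 4 and 2 rose and 3, 2 and 3 fell (5, 5 and 3 rose and 3, 3 and 3 fell adjusted over the list alone; camera adjusted p = 0.0589, 0.295 and 0.966), with Atf4 at 1.2 ± 0.24 and 1.46 ± 0.27 in gastrocnemius and quadriceps. Fold changes of sick against healthy and of sick against wild type share the sick libraries. Across genes they correlated with r = 0.824, 0.882 and 0.821 (covariance 0.630, 0.565 and 0.596), against 0.538, 0.555 and 0.562 (covariance 0.137, 0.151 and 0.163) in simulations of unchanged groups. They had 748, 1061 and 659 higher and 577, 711 and 659 lower genes in common. Fold changes of sick and of healthy mutants against the same wild-type libraries correlated with r = 0.172, 0.320 and 0.480 (covariance 0.0757, 0.102 and 0.227), against 0.428, 0.463 and 0.467 (covariance 0.102, 0.118 and 0.126) in simulations. With each mutant group set against a different pair of wild-type libraries, r averaged 0.00849, 0.151 and 0.296 (covariance 0.00312, 0.0556 and 0.161).

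A test over all 32 libraries asked whether the changes differ between muscles. For sick against wild type, 37 of 15229 genes passed, and 582 had an unadjusted p under 0.05. For healthy against wild type the numbers were 42 and 494. The smallest adjusted p belonged to genes known from the kidney, in both comparisons. For Umod it was 2.47e-06 and 4.17e-08, for Slc12a1, a salt transporter of the kidney tubule, 0.000134 and 6.32e-05, and for Miox, an enzyme of the kidney tubule, 0.000235 and 6.32e-05. Their summed wild-type counts were 1, 0 and 238 for Umod, 3, 1 and 174 for Slc12a1 and 1, 0 and 218 for Miox. Pdzk1ip1, Slc22a12 and Slc17a3 followed in the sick comparison (adjusted p = 0.000235, 0.000337 and 0.000731). Slc17a3, Cdh16 and Mep1a followed in the healthy one (adjusted p = 7.69e-06, 3.83e-05 and 8.87e-05). Csrp3 and Ankrd1 of the sarcomere, chosen after their values were seen, also passed in the sick comparison (adjusted p = 0.00812 and 0.0087). The estimates of this model in the 3 muscles were 1.93 ± 1.0, 4.37 ± 1.0 and -3.86 ± 0.99 for Csrp3, and for Ankrd1 3.49 ± 0.61, 3.04 ± 0.62 and -1.26 ± 0.63. With same-numbered libraries of a state taken as 1 mouse, Csrp3 and Ankrd1 did not pass (adjusted p = 0.134 and 0.157). Nor did they without tibialis sick replicate 2 (adjusted p = 0.0637 and 0.103), and the count was 16. It was 23 without tibialis sick replicate 4. Without the genes over 10 times higher in wild-type tibialis, the counts for sick and healthy were 5 and 8.

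The wild-type libraries alone give the differences between the muscles. Hoxc6 and Hoxc8 were higher in quadriceps than in gastrocnemius, at 1.85 ± 0.20 and 2.06 ± 0.32 (adjusted p = 0.000582 and 0.00683). Hoxa11 and Hoxa13 were lower, at -3.75 ± 0.48 and -3.98 ± 0.37 (adjusted p = 0.00214 and 0.000346). Tbx1, a T-box factor, was higher in quadriceps, at 2.72 ± 0.40 (adjusted p = 0.00457), and Ugt8a, an enzyme of galactolipid synthesis, lower, at -3.93 ± 0.41 (adjusted p = 0.000368). In tibialis Ugt8a and Mss51, a muscle zinc-finger gene, were below gastrocnemius, at -3.35 ± 0.41 and -4.48 ± 0.46 (adjusted p = 0.000536 and 0.000127). Tibialis lay above gastrocnemius and quadriceps in Kap, at 8.34 ± 0.49 and 9.20 ± 0.53 (adjusted p = 3.31e-06 and 2.57e-06). Kap and other kidney genes higher in tibialis may be carried-over RNA. The adipocyte genes Lgals12 and Retn were lower in tibialis than in quadriceps, at -3.70 ± 0.48 and -3.46 ± 0.60 (adjusted p = 0.000847 and 0.00624). Of 14708 genes tested, 158 differed between quadriceps and gastrocnemius (22 higher, 136 lower), 380 between tibialis and gastrocnemius (186 higher, 194 lower) and 834 between tibialis and quadriceps (527 higher, 307 lower). The first count was 71 and 67 without gastrocnemius replicates 2 and 3, and 82, 60 and 50 without quadriceps replicates 1 to 3. The second was 207 without gastrocnemius replicate 2, and 197, 186 and 238 without tibialis replicates 1 to 3. The third was 368, 315 and 296 without quadriceps replicates 1 to 3, and 453, 448 and 420 without tibialis replicates 1 to 3. Lgals12 and Retn did not pass in a fit of all 32 libraries (adjusted p = 0.0900 and 0.121).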

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

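The tests on kidney transcripts and on single genes in this part were chosen only after the results were seen, while the measures compared between libraries of a group were fixed by rule. In 65 comparisons of 13 measures over 5 groups of 4 libraries, 5 libraries lay apart from the other 3 of their group, and chance alone picks about 1 in 20 groups. Quadriceps healthy knock-in replicate 3 had a total of 30.7 M (mega) counts against 7.69 to 9.98 M in the other 3. In gastrocnemius wild-type replicate 3, the 10 genes with most counts took 21.2% of all counts against 25.6 to 26.1%. Tendon markers averaged 4.17 on the log2(CPM + 1) scale in quadriceps wild-type replicate 4, against 5.05 to 5.06 in the others. Adipocyte markers averaged 8.80 in quadriceps healthy knock-in replicate 4, against 4.30 to 4.80. Endothelial markers averaged 5.30 in tibialis wild-type replicate 4, against 5.78 to 5.84.

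Genes known from the kidney showed the smallest p in the test of whether a change differs between muscles, and they were high in the 4 wild-type tibialis libraries. For sick knock-in against wild type the adjusted p was 2.47e-06 for Umod, 0.000134 for Slc12a1, 0.000235 for both Miox and Pdzk1ip1, 0.000337 for Slc22a12 and 0.000731 for Slc17a3. For healthy knock-in against wild type it was 4.17e-08 for Umod, 7.69e-06 for Slc17a3, 3.83e-05 for Cdh16, 6.32e-05 for both Slc12a1 and Miox and 8.87e-05 for Mep1a. In 0 of the 2 other muscles was every wild-type library above every knock-in library in the summed CPM of kidney markers. This leaves open whether the knock-in lowers them in every muscle, since of 12 markers that passed these tests only 5 and 3 had at least 10 counts in wild-type gastrocnemius and quadriceps. A candidate explanation is kidney RNA carried over into the wild-type tibialis libraries, for which the test asked that over 80% of the kidney markers with enough counts be higher there than in any other library, and 75% (18 of 24) were. Cyp4b1, the most abundant, was at 13.9 to 22.3 CPM there and at up to 14.7 CPM elsewhere. Of these 24, 12 had already passed the tests that prompted this check, and of the 12 that had not, 6 were higher, while 5 of the 24 exceeded 1 CPM elsewhere. It cannot be told apart from a difference in the tibialis of the wild-type mice, because all 4 libraries of that group share the pattern, at 50.7 to 74.6 CPM, and the next highest library, gastrocnemius healthy replicate 2, held 23.6 CPM.

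Csrp3 and Ankrd1, genes of the sarcomere, also passed the test between muscles in sick knock-in against wild type, with adjusted p of 0.00812 and 0.00870. The log2 fold changes in the 3 muscles were 1.93 ± 1.0, 4.37 ± 1.0 and -3.86 ± 0.99 for Csrp3 and 3.49 ± 0.61, 3.04 ± 0.62 and -1.26 ± 0.63 for Ankrd1 (estimate ± SE). Without tibialis sick replicate 2 the adjusted p was 0.0637 and 0.103. With same-numbered libraries of a state taken as 1 mouse it was 0.134 and 0.157. No explanation was tested.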

How the results depend on the processing

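Fits by limma-trend, fits without the genes over 10 times higher in wild-type tibialis, list tests without quadriceps healthy replicate 4 and fits without sick knock-in replicate 2 or wild-type replicate 4 in every muscle were chosen after the data were seen, and the other settings before. Of the counts of genes or lists, 65 of 127 values at settings other than leaving out a library stayed within 1.5 times the value reported and 62 did not. Among the genes named, 2481 of 2576 values kept direction and side of the threshold, 94 no longer passed, 1 came to pass and 0 reversed. Gne passed in none of 121 values (log2 fold change -0.17 to 0.27, smallest adjusted p 0.502). RLE factors in place of TMM moved no count beyond 1.5 times and ended none of the calls of named genes. The causes of the changes below were not tested, except that fits with fewer libraries or groups have fewer degrees of freedom by construction. Values for gastrocnemius, quadriceps and tibialis are in this order.

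With only the 2 groups compared in the model, sick knock-in against wild type gave 1231 genes in gastrocnemius and 1236 in tibialis, healthy knock-in against wild type 2 in quadriceps, and sick against healthy knock-in 366 in quadriceps and 95 in tibialis. Changed the same way in all 3 muscles were then 357 genes for sick knock-in against wild type and 37 for sick against healthy knock-in. With all 32 libraries in 1 model the counts were 3280 in gastrocnemius for sick knock-in against wild type, 10 and 9 in gastrocnemius and quadriceps for healthy knock-in against wild type, and 2951 in tibialis for sick against healthy knock-in. The counts over all 3 muscles were then 1221, 5 and 1127 for the 3 comparisons in that order, and wild-type muscles differed by 92 (quadriceps against gastrocnemius) and 221 genes (tibialis against gastrocnemius). With no filter on low counts, healthy knock-in against wild type gave 7 genes in gastrocnemius and 123 in tibialis, and sick against healthy knock-in 1458 in quadriceps and 1086 in tibialis. The counts over all 3 muscles were 464, 3 and 326, and 88 and 87 genes differed between muscles in their change in sick and in healthy knock-in. Limma-trend gave 2 genes for healthy knock-in against wild type in gastrocnemius, 2 in quadriceps and 2 over all 3 muscles, and 99 for quadriceps against gastrocnemius in wild type. Without the genes over 10 times higher in wild-type tibialis, 36 genes changed in healthy tibialis, and 5 and 8 differed between muscles in sick and healthy knock-in. Without sick knock-in replicate 2 in each muscle, 37 genes changed the same way in all 3 against wild type and 64 against healthy knock-in. Without wild-type replicate 4 in each muscle, 7 did for healthy knock-in against wild type.

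Leaving out each library in turn gave 561 to 2547, 83 to 4249 and 957 to 3043 genes for sick knock-in against wild type. It gave 1 to 9, 2 to 13 and 55 to 68 for healthy knock-in against wild type, and 728 to 2394, 287 to 4096 and 266 to 2299 for sick against healthy knock-in. Genes whose change differs between muscles numbered 16 to 40 for sick and 33 to 51 for healthy knock-in. Wild-type muscles differed by 50 to 220 (quadriceps against gastrocnemius), 186 to 482 (tibialis against gastrocnemius) and 296 to 1187 genes (tibialis against quadriceps).

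Camera with an estimated correlation called 0 lists in every comparison, where the preset correlation called 15, 14 and 17 for sick knock-in against wild type, 11, 15 and 8 for healthy knock-in against wild type and 13, 11 and 14 for sick against healthy knock-in. Fry, which does not compare a list with other genes, called 9, 9 and 3, then 0, 0 and 0, and 5, 6 and 7 lists. Without quadriceps healthy replicate 4, camera with the preset correlation called 14 lists in healthy quadriceps.

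Same-numbered libraries of different states did not pair, since 6 of 29 pairs correlated above 0.1 in their deviations from the group means, and 10 of 58 libraries correlated best with their own number. Across muscles, 26 of 28 pairs correlated above 0.1 and 50 of 56 libraries correlated best with their own number. With the number as a replicate block, sick knock-in against wild type gave 879 genes in quadriceps and 1260 in tibialis, healthy knock-in against wild type 11 in gastrocnemius and 2 in quadriceps, and sick against healthy knock-in 1295 in quadriceps and 576 in tibialis. The counts over all 3 muscles were 276 and 210 for sick knock-in against wild type and against healthy knock-in, wild-type muscles differed by 253, 704 and 1610 genes, and 13 lists were called in healthy tibialis. Of 185 values of named genes, 11 no longer passed with the block. In the test between muscles, with libraries of 1 number and state taken as 1 mouse, Csrp3 and Ankrd1 no longer passed (adjusted p = 0.134 and 0.157).

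Over all settings, the limma adjusted p of the named calls that some setting ended ran as follows. In quadriceps, sick knock-in against wild type, the ranges were Ctxn3 2.88e-05 to 0.0577, Gnmt 0.000173 to 0.0517, Eif4ebp1 7.24e-05 to 0.0550, Foxo3 0.00210 to 0.0598, Nfkbia 0.000922 to 0.0550, Igf1r 0.000776 to 0.0550, Cdkn1a 0.000533 to 0.0517, Serpinh1 0.00395 to 0.0826, Smoc2 0.000145 to 0.0732, Col15a1 0.00577 to 0.0551, Igtp 0.00576 to 0.0974, Lyz2 0.00216 to 0.0788, Rps6 0.00309 to 0.0559, Rpl10a 0.00621 to 0.0559, Cycs 0.00102 to 0.0550 and Sgcd 0.00709 to 0.0696. In tibialis they were Gnmt 0.00195 to 0.0525, Fbxo32 0.00939 to 0.0595, Col3a1 0.000649 to 0.0511, Col1a2 0.00334 to 0.0609, Cryab 0.000394 to 0.0523 and Uqcrc1 0.00746 to 0.0618, and in gastrocnemius Cycs 0.00131 to 0.0565 and Slc4a1 0.00531 to 0.0808. For healthy knock-in against wild type they were Hint2 0.00567 to 0.334, Galt 0.0400 to 0.419 and Gm1840 0.000299 to 0.762 in quadriceps and Gprc5c 0.0154 to 0.104 in tibialis. For sick against healthy knock-in they were Sesn1 0.000229 to 0.0535, Stc2 0.000551 to 0.0515, Nrep 0.000367 to 0.0515, Nmrk2 0.000825 to 0.0559, Eif4ebp1 0.00155 to 0.0577 and Col1a2 0.00313 to 0.0632 in tibialis and Csrp3 0.00122 to 0.0634 in gastrocnemius. Between wild-type tibialis and quadriceps they were Lgals12 5.21e-05 to 0.0900 and Retn 0.00344 to 0.121, and in the test between muscles 0.00238 to 0.134 for Csrp3 and 0.00452 to 0.157 for Ankrd1. At this depth and number of libraries, the simulated 2-fold changes recovered were 15 to 42 of 100, so a gene that did not pass is not shown to be unchanged. The planned quasi-likelihood test of the counts, the DESeq2 Wald test and the DESeq2 likelihood ratio test of the interaction were not run. Limma-voom took the place of the first.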

Other observations

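All tests in this part were chosen only after the results were seen, except those on reads of Vcp, on library depth and on the ratio of changes in sick knock-in replicate 2. Some genes of mast cells, which are in none of the lists above, were higher in sick quadriceps. Tpsab1, a mast cell tryptase, rose by 4.91 ± 0.42 on the log2 scale against wild type (adjusted p = 0.00040), Hdc, the histidine decarboxylase gene, by 2.42 ± 0.32 (adjusted p = 0.00593) and Tpsb2 by 1.53 ± 0.39 (adjusted p = 0.0252). Of 9 measured genes of a list of 10, 1, 3 and 0 rose and none fell in the 3 muscles by limma. A larger share of mast cell RNA may accompany sickness. It would raise the list in every muscle, and fry found it higher, on balance, in 1 of 3 (adjusted p = 0.551, 0.00241 and 0.843 over the 3 muscles), so that it cannot be told apart from changes within cells. In quadriceps camera's unadjusted p was 0.0912 with an estimated correlation.

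Vcp-rs was near 0 in both knock-in states of every muscle. Over all genes, 49 had an unadjusted p under 0.05 and 1 sign in the 3 muscles for healthy knock-in against wild type, and 32 of them kept that sign in the sick mice, both comparisons sharing the wild-type libraries. Reads of a shared sequence that moved from Vcp-rs to Vcp are argued against, since Vcp changed by -17.6% of what Vcp-rs lost (median of the muscles, which gave -4.74%, -60.0% and -17.6%). Reads left uncounted because both copies match them would not raise Vcp, so the test cannot speak to those. A candidate explanation for part of these genes, a stretch of chromosome 4 around Gne brought by the targeted allele, is left open. Whether it bears on Vcp-rs (chromosome X) was not tested. Of 125 tested genes within 10 Mb of Gne, 3 were among the 49 (0.452 expected, odds ratio 7.15, one-sided Fisher's exact test, p = 0.0104), but 2 of the 3 had already been called in some muscle, and without the 4 genes so called (Hint2, Galt, Gm13305 and Gm2564) 1 of 121 was among the other 47 (0.420 expected, p = 0.344).

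Sick knock-in replicate 2 lay farthest from wild type. Over the 24 atrophy genes its mean log2 difference from wild type was 2.22, 2.49 and 2.99 in the 3 muscles, against 0.91 and 2.09, 2.12 and 1.03, and 1.04 and 1.11 in the other sick libraries and 0.939 and 0.907 in healthy replicate 4 of quadriceps and tibialis. Library depth is argued against, since after thinning to the depth of the shallowest other sick library the mean was 2.22, 2.47 and 2.98, still highest in 3 of 3 muscles, but a fault of a single library is left open, since the lead over the next sick library exceeded the SD of the wild-type libraries in tibialis alone (1.87 against 0.319). A larger form of the change in the other sick mice is a hypothesis consistent with the median ratio of its changes to theirs, which was 1.06, 1.28 and 1.27, while the other sick libraries gave 0.314 to 0.933. Whether the number marks 1 mouse is not stated in the labels. Ddx3y, a gene of the Y chromosome, was at 34.0, 47.3 and 31.2 CPM in the replicate 2 libraries and at 42.1 to 117 CPM in all other libraries.

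Wild-type replicate 4 differed from the other wild-type libraries at some genes. Gm1840 was at 13.8 to 14.5 CPM in its 3 libraries, at most 0.724 CPM in the other wild-type libraries and 15.5 to 53 CPM in the knock-in libraries. Gm13365 was at 19.5 to 21.7 CPM in them, at most 0.170 in the other wild-type and 3.41 to 12.8 in the knock-in libraries, and Gm5452 at 59.8 to 74.8, at most 0.283 and 11.2 to 41.0 CPM. Klk1b3 was at 0.199 to 3.36, at most 0.0341 and 0 to 14.6 CPM, and Klk1b16 at 1.72 to 8.76, at most 0.0535 and 0 to 12.1 CPM. These genes were chosen after their values were seen.

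Other splits of the libraries into groups of the same sizes were fitted alike. The number with as many genes as the real split is given, itself included, unadjusted over tests. For sick knock-in against wild type 1 of 35 splits, the lowest share possible, reached the 2087, 2488 and 2621 genes of the 3 muscles. The highest others, 61, 178 and 2, set wild-type replicates 1, 2 and 3 against all others. For healthy knock-in against wild type the real split led in tibialis (72 genes, 1 of 35, highest other 2). It did not in gastrocnemius (1 gene, 5 of 35, highest other 14) or quadriceps (5 genes, 2 of 35, highest other 40). The splits with 14 and 40 genes point to a structure of the samples. Both put wild-type replicate 4 with healthy knock-in libraries and healthy replicate 2 with the other wild-type libraries. For sick against healthy knock-in the real split led in quadriceps and tibialis (2431 and 1646 genes, 1 of 35 each, highest others 251 and 52). In gastrocnemius 10 splits are too few for a share under 0.05 (1991 genes, 1 of 10, highest other 0). Against wild type, sick knock-in gave 778 genes changed alike in all 3 muscles and healthy 1 (1 of 35 each, highest other 0). For sick against healthy knock-in 20 splits are too few (600, 1 of 20, highest other 0). No other of 35 splits reached the 37 and 42 genes whose change differs between muscles (highest other 0). Nor did any reach the 158, 380 and 834 differing between wild-type muscles (highest other 0, 1 and 1). The 72, 37, 42, 380 and 834 include kidney genes of wild-type tibialis, possibly carried over.

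The number of gene lists called by camera was reached by chance more often. For sick knock-in against wild type 8, 14 and 8 of 35 splits called as many lists as the real 15, 14 and 17, with highest others of 19, 18 and 22. For healthy knock-in against wild type 26, 20 and 32 of 35 did (real 11, 15 and 8; highest others 19, 23 and 24). For sick against healthy knock-in 26 and 20 of 35 did in quadriceps and tibialis (real 11 and 14; highest others 18 and 25), so chance was not excluded in any of these. In gastrocnemius 10 splits are too few (10 of 10, real 13, highest other 21).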
